A study of Mus musculus with 72 samples.

How the data were processed

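Total RNA from frozen colon of 72 mice was hybridised to 2-colour Agilent arrays, per the labels' protocols, after amplification of 500 ng. The mouse's RNA carried Cy3 and a common reference carried Cy5. The reference was pooled RNA of adult intestine, kidney and liver plus fetus of Swiss mice. No array had the dyes exchanged, so a dye effect of a feature is shared by all arrays and cancels in differences between mice. The mice were kept in conventional housing and inoculated with Enterococcus strains and intestinal flora, per the labels' protocols. The growth protocol of each array names AIN76A as the feed, and the diet was taken from the diet label instead. The design text names intact proximal colon and colon epithelium, and every array carried the tissue label colon. The animals are separate mice, so the spread between arrays of a group includes the spread between animals. The array positions in the titles gave 18 slides of 4 arrays.

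The authors deposited 1 table of log2 ratios with a column for each of the 72 arrays, and the submitters' processing notes name limma and R 2.14.1. The base of the log was taken from limma's convention and from the range of the values. Background correction, normalization and the numerator of the ratio are not given in the sources used here. The table had 45018 rows, numbered up to 45220, with no missing values. Array medians were between -0.01 and 0.01, so the ratios had been centred within arrays. The SD of an array's values was between 0.78 and 1.01, so the arrays had not been brought to a single distribution. Correlations between arrays were between 0.72 and 0.98. No 2 arrays of a group held identical values, and the smallest SD of a difference between such arrays was 0.18. Values were used as deposited, with no filter, no pseudocount and no change of sign. Scanner intensities were not used here, so features near background could not be set aside and the signal behind a ratio is unknown.

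The row numbers could not be matched to genes with the table of gene symbols at hand. The gene lists fixed before the data were examined, the test of their shifts, the rule for named genes and the check of the ratio's direction by marker genes were therefore not run. Control spots and replicate spots could not be told apart from other spots by name. Counts are counts of features, not genes. For each main comparison the 2 features with the largest rise and the 2 with the largest fall among those past the threshold were named.

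Tests were made with limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 12 groups was fitted to all 72 arrays with lmFit, variances were moderated with eBayes, and p-values were adjusted with the Benjamini-Hochberg method within each comparison over 45018 features at a threshold of 0.05. Contrasts covered the strains over all diets and on each diet, diets within each strain, and the interaction of strain and diet. F tests covered all 6 diets, the 3 milk diets and the whole interaction. If no feature differed, a share of 0.05 of the 45018 features would on average have an unadjusted p under 0.05 by chance. Features are not independent, and the spread of this share was not computed. A count above or below it is therefore not evidence by itself for or against an effect. The histology level was tested in a model with a term per strain beside the 12 group means. The procedure was tested on simulated data with 200 changed features among 45018. For 36 against 36 mice it recovered 98.5% of 1.5-fold changes with 8 false calls. For 6 against 6 mice, simulated after cow milk against AIN76A in the knockout, it recovered 83% of 1.5-fold and 96% of 2-fold changes, with 7 and 15 false calls. The real arrays of modified AIN76A and AIN76A in the knockout were also split in other ways. These splits gave up to 440 features, with a median of 0. The simulated false calls therefore do not bound those in the real arrays.

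A position on the strain axis was computed for each mouse, a summary chosen after the data were examined because the features have no names. The axis was the difference between the knockout and C57BL/6J means over diets that were not part of the comparison, and the position was the projection of a mouse on it, scaled to 0 at the C57BL/6J and 1 at the knockout mean. For a comparison of a diet with AIN76A the axis came from the 4 other diets, so that neither group compared defined it. For single mice and for histology levels it came from the 5 diets other than the mouse's own. Positions were compared with two-sided exact permutation tests, or with 100000 resamples within diet groups for histology levels. The p-values were adjusted together over 20 tests. Positions were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

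Alternatives chosen before the data were examined were slide as a random or fixed block, quantile normalization between arrays, centring on the array median, a fit to the compared groups alone, the histology level as a term, a robust variance model, array weights, only the features with an SD above the median, a minimum fold change of 1.5, and leaving out each slide. Slides shared a correlation of 0.11 between their arrays. Alternatives chosen after the data were examined were merging near-identical spots, which left 42415 features, and leaving out 8 arrays whose residual spread exceeded the median by 3 median absolute deviations. The arrays' slides were the batches tested.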

Results

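Colon RNA of 72 male mice was measured on 2-colour oligonucleotide arrays, 1 array per mouse. The mice belonged to 2 strains: Il10 knockout mice, which lack the anti-inflammatory cytokine interleukin-10 and are used as a model of colitis, and C57BL/6J mice, the background strain. Mice of each strain received 1 of 6 diets for 6 weeks and were sampled at 12 weeks of age. The diets were AIN76A (a purified rodent diet that served as a control), a modified AIN76A whose modification the labels do not state, cow milk, goat milk, sheep milk and soy. Each of the 12 groups held 6 mice, of which 3 carried a high and 3 a low colon histology score level within their group. The deposited values were log2 ratios between the mouse's RNA and a common reference pool for 45018 array features. The features carried numbers without gene names, so features are reported by number, the Il10 transcript was not identified, and no gene group was tested. The labels do not state which channel is the numerator, so "higher" and "lower" describe the deposited ratio and not RNA abundance. The number of arrays limits the precision. The signal behind the ratios is not known.

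The first comparison asked how the colon of Il10 knockout mice differed from that of C57BL/6J mice. Over all 6 diets, 20897 features differed between the 36 knockout and the 36 C57BL/6J mice (limma, adjusted p under 0.05), of which 11553 had a higher and 9344 a lower ratio in the knockout. Most of these differences were small, with a median size of 0.23 on the log2 scale. Among the called features, 409 were at least 2-fold higher and 639 at least 2-fold lower in the knockout. Feature 43313 had the largest rise, from -2.56 ± 0.68 in C57BL/6J to 0.75 ± 1.41 in the knockout (SD, n = 36 each), followed by feature 20240, which rose from -0.38 ± 0.35 to 2.56 ± 0.73. Feature 23736 had the largest fall, from 3.09 ± 1.82 in C57BL/6J to -1.32 ± 0.53 in the knockout, followed by feature 11405, which fell from 1.83 ± 1.95 to -2.36 ± 0.50. For 192 features the values of all 36 knockout mice lay apart from those of all 36 C57BL/6J mice, 68 of them higher and 124 lower in the knockout. No feature separated the mice in this way in any other of 100 splits of the strains within diets. The strain difference was present within every slide. Over the 18 slides of 4 arrays each, the difference between the knockout and C57BL/6J arrays of a slide had a slope of 0.60 to 1.38 on the strain difference of the other slides.

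The strain difference was also tested on each diet, with 6 knockout and 6 C57BL/6J mice. On AIN76A, 14656 features differed between the strains, 8646 higher and 6010 lower in the knockout. On soy 11684 features differed, and on sheep milk 10563. The order of these 3 diets was not stable, since with slide as a fixed block the counts were 10090 on AIN76A, 12091 on soy and 10101 on sheep milk. On modified AIN76A, cow milk and goat milk the counts were 6999, 6786 and 4767. The interaction of strain and diet was itself past the threshold for 2840 features, or 1761 with slide as a fixed block. Against AIN76A, the strain difference changed for 1964 features on cow milk, 1650 on goat milk, 429 on modified AIN76A and 3 on soy. With slide as a fixed block these counts were 198, 45, 0 and 3. The cow milk count became 1132 without slide 7 and 1269 without 8 arrays of large residual spread, and the goat milk count 889, 1087, 965 and 1076 without slides 4, 8, 9 and 11. The 429 features became 21 when the fit was restricted to the arrays compared, 10 with array weights, 1 without slide 1, 77 without slide 2, 0 without slide 3 or slide 11, and 1104 without slide 10. No feature passed the threshold for sheep milk in limma, where 3637 features had an unadjusted p under 0.05, more than the chance share. The spread of the chance share was not computed, so a count above or below it, here and later, decides nothing by itself.

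**Figure D1:**
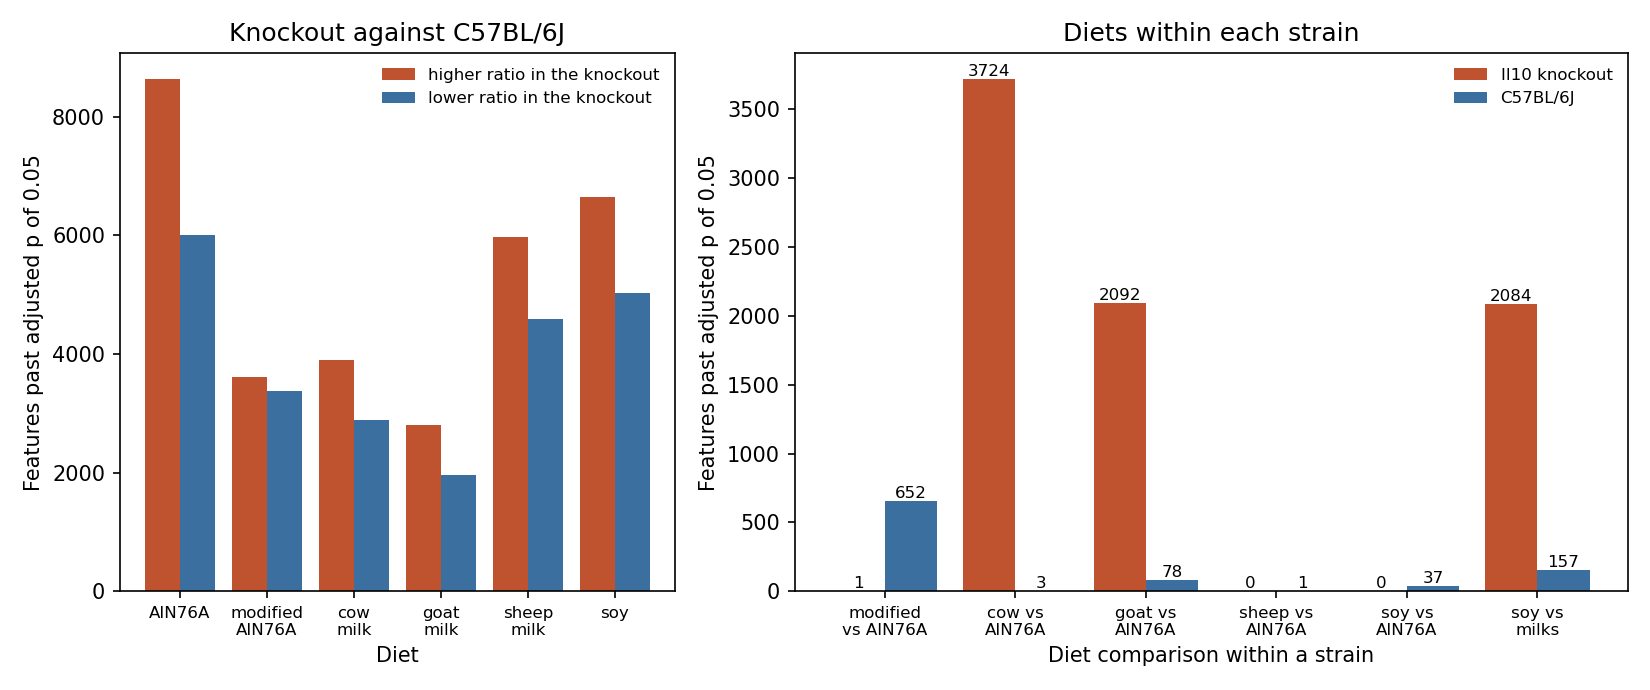
Features past the adjusted p threshold of 0.05 in limma, out of 45018 tested. The left bars count features with a higher or lower deposited ratio in the knockout than in C57BL/6J on each diet, with 14656 in all on AIN76A and 4767 on goat milk. The right bars count features that differed between diets within each strain, with 3724 for cow milk against AIN76A in the knockout and 3 in C57BL/6J.

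The next comparisons asked whether milk diets changed the colon of Il10 knockout mice. Diet changed 3990 features over the 6 diets in the knockout. Among the comparisons with AIN76A, cow milk and goat milk gave the most changed features. Cow milk changed 3724 features, 1952 higher and 1772 lower, and goat milk changed 2092 features, 1287 higher and 805 lower. With slide as a fixed block these counts were 2135 and 878, and with the fit restricted to the arrays compared 2384 and 996. A minimum change of 1.5-fold left 1361 and 923. The goat milk count was also 1122 without slide 9 and 3338 with array weights. Sheep milk changed no feature in limma, where 2025 features had an unadjusted p under 0.05, fewer than the chance share. For sheep milk, array weights gave 5 features and leaving out the 8 arrays of large residual spread gave 3. Leaving out slide 3 or slide 5 gave 1 each. The 3 milk diets combined changed 2209 features against AIN76A, 1208 higher and 1001 lower, which fell to 412 with slide as a fixed block. Without slide 6 the balance turned to 1334 higher and 1393 lower, and for cow milk alone to 1869 higher and 2092 lower. Over the 2209 features the median size of the change was 0.41 without the block and 0.35 with it, and the standard error at the median variance was 0.07 without it and 0.08 with it. Another split of the same knockout mice gave 2390 features, so chance is not excluded for the count of 2209. The counts of cow milk alone and goat milk alone were not compared with other splits. Feature 32583 had the largest rise with cow milk, from -3.23 ± 0.33 on AIN76A to 0.10 ± 0.76 (SD, n = 6 each). Its mean on goat milk was -0.77 ± 1.41, and the means on modified AIN76A, sheep milk and soy were -3.21 ± 0.39, -2.89 ± 0.82 and -3.43 ± 0.37. Feature 29857 rose from -2.94 ± 0.69 on AIN76A to 0.21 ± 0.73 on cow milk. The largest falls were in feature 35725, from 6.11 ± 0.55 to 3.80 ± 1.56, and in feature 9284, from 0.53 ± 0.56 to -1.65 ± 0.55. In C57BL/6J mice on AIN76A the means of features 32583 and 9284 were 0.51 ± 1.10 and -2.27 ± 0.16.

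The milk diets were also compared with each other. In the knockout the 3 milk diets differed in 1308 features. Cow milk differed from sheep milk in 1555 features and goat milk from sheep milk in 879. No feature differed between cow milk and goat milk in limma, where 1000 had an unadjusted p under 0.05, fewer than the chance share. The goat and sheep milk groups differed in only 5 features when the fit was restricted to the arrays compared, in 285 without slide 5, in 35 without slide 9 and in 467 without slide 17. The cow and sheep milk groups differed in 825 without slide 5, in 756 when the fit was restricted to the arrays compared and in 2554 with slide as a fixed block. Among C57BL/6J mice, 1 feature differed between the 3 milk diets.

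Most features that cow or goat milk changed in the knockout moved towards the C57BL/6J values. Of the 3724 features changed by cow milk, 3192 (85.7%) moved in the direction of C57BL/6J, where the direction was taken from the strain difference on the 4 diets other than cow milk and AIN76A. Of the 2092 features changed by goat milk, 1843 (88.1%) did so. Over all features, called or not, the shares were 63.0% for cow milk and 64.3% for goat milk. Across all features, which are not independent replicates, the cow milk effect had a correlation of -0.54 with that strain difference, and the goat milk effect likewise -0.54. The corresponding correlations were -0.32 for modified AIN76A, -0.18 for sheep milk and 0.01 for soy. With slide effects removed the values were -0.50 for cow milk, -0.44 for goat milk, -0.19 for modified AIN76A, 0.16 for sheep milk and 0.22 for soy. To compare mice rather than features, each mouse was placed on an axis where 0 was the C57BL/6J mean and 1 the knockout mean of the diets not compared. In the knockout, mice on cow milk lay at 0.73 ± 0.10 and mice on AIN76A at 1.12 ± 0.12 (SD, n = 6 each, difference -0.40, two-sided exact permutation p = 0.00216, adjusted p = 0.0216 over 20 tests). That is the smallest p that 6 against 6 mice can give, since each of the 6 cow milk mice lay below each of the 6 AIN76A mice. Goat milk mice lay at 0.78 ± 0.19 against 1.13 ± 0.11 on AIN76A (difference -0.35, exact permutation p = 0.00866, adjusted p = 0.0289). Cow milk mice also lay below sheep milk mice (difference -0.32, exact permutation p = 0.00433, adjusted p = 0.0289). Goat milk mice differed from sheep milk mice by -0.26, which did not pass the adjustment (exact permutation p = 0.0498, adjusted p = 0.0905). Sheep milk and soy mice differed from AIN76A mice by -0.08 and 0.003, with exact permutation p of 0.411 and 0.983. With slide effects removed, the cow and goat milk differences from AIN76A were -0.33 and -0.25, and those of sheep milk and soy 0.06 and 0.09. Only 1 slide held knockout mice of both cow milk and AIN76A and 2 slides held both goat milk and AIN76A, so no difference was computed within slides.

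**Figure D2:**
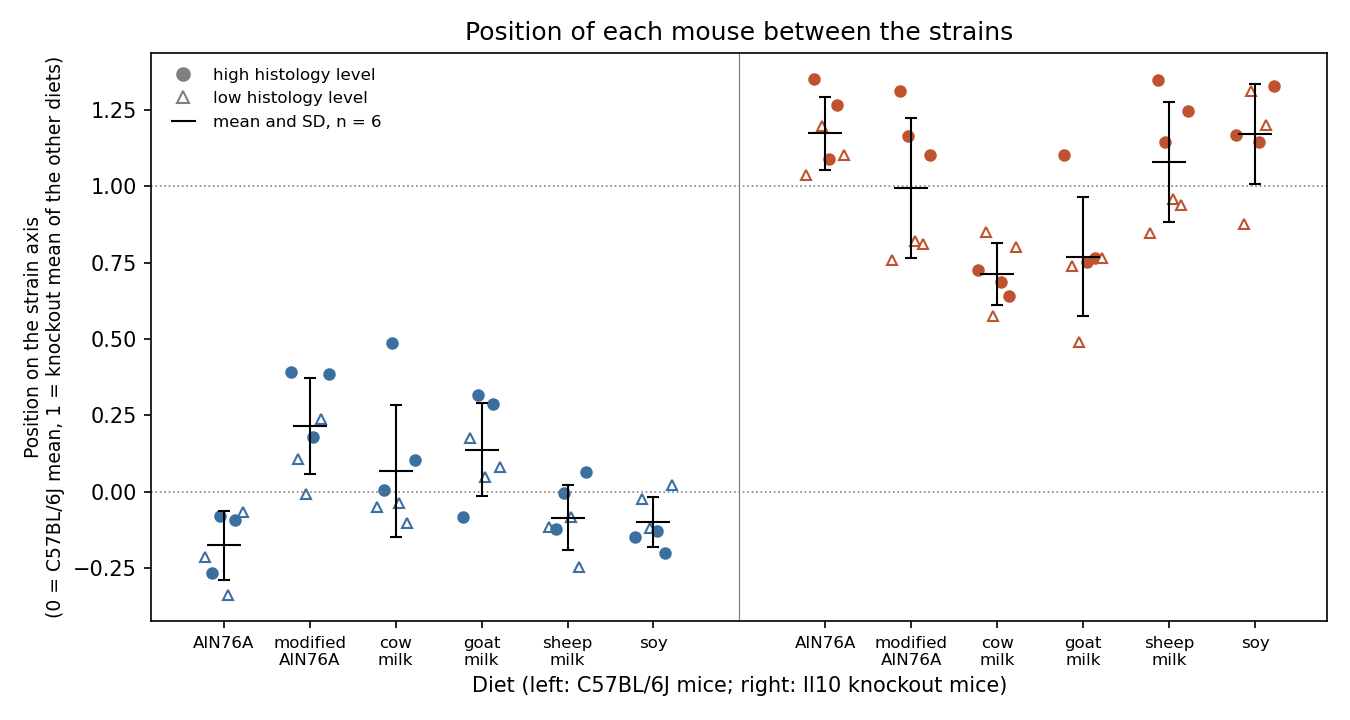
Position of each mouse on the strain axis, by diet, with C57BL/6J mice on the left and Il10 knockout mice on the right. The axis is unitless, with 0 the C57BL/6J mean and 1 the knockout mean of the 5 other diets. Filled circles are mice of a high and open triangles mice of a low histology level, and bars show the mean and SD of 6 mice. Knockout mice on cow milk had a mean of 0.71 and those on AIN76A 1.17.

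The milk diets changed few features in C57BL/6J mice. Diet changed 450 features over the 6 diets, and the milk diets together changed 46 against AIN76A, 30 higher and 16 lower. This balance turned to 2 higher and 10 lower with slide as a fixed block, 2 higher and 13 lower when the fit was restricted to the arrays compared, and 5 higher and 10 lower without slide 2. With array weights it was 11 and 11, with a minimum change of 1.5-fold 9 and 11, without the 8 arrays of large residual spread 50 and 57, and without slides 4, 7 and 18 it was 9 and 10, 7 and 9, and 8 and 11. Only 3 features were left without slide 6 and 1 without slide 11. With near-identical spots merged 11 were left, 9 higher and 2 lower. Cow milk changed 3 features, goat milk 78 and sheep milk 1, or 0, 38 and 0 with slide as a fixed block. The cow milk count was 16 when the fit was restricted to the arrays compared. Leaving out a slide gave 39 (slides 6 and 11) to 152 (slide 1) for goat milk. Leaving out the 8 arrays of large residual spread gave 190 for goat milk, and merging near-identical spots gave 50. The milk effects in C57BL/6J and in the knockout had a correlation of -0.31 across features. Of the 78 features changed by goat milk in C57BL/6J, 77 moved in the direction of the knockout. Of the 46 changed by the milk diets together, 42 did so. The 3 cow milk features also did, and the 1 sheep milk feature did not. Over all features, called or not, 40.1% for goat milk and 44.5% for the milk diets moved in the direction of C57BL/6J. On the strain axis, goat milk mice of C57BL/6J lay at 0.11 ± 0.16 and AIN76A mice at -0.15 ± 0.11 (difference 0.25, exact permutation p = 0.00866, adjusted p = 0.0289). The cow milk difference was 0.20 (exact permutation p = 0.039, adjusted p = 0.0866). With slide effects removed the goat and cow milk differences were 0.17 and 0.15.

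Soy was compared with AIN76A and with the milk diets. In the knockout no feature changed on soy against AIN76A in limma, where the smallest adjusted p was 0.419. An unadjusted p under 0.05 was found for 2251 features, which is about the chance share. Against the 3 milk diets, 2084 features differed in the knockout, 976 higher and 1108 lower on soy, or 837 with slide as a fixed block, 420 higher and 417 lower. The balance turned to 846 higher and 791 lower when the fit was restricted to the arrays compared, 2191 and 2013 with array weights, 849 and 846 without slide 1 and 941 and 930 without slide 12. Without slides 8 and 16 the counts were 1101 and 919. Another split of the same knockout mice gave 2166, so chance is not excluded for the count of 2084. Soy changed 37 features against AIN76A in C57BL/6J mice, 6 higher and 31 lower, and 157 against the milk diets, 23 higher and 134 lower. When the fit was restricted to the arrays compared, the 37 features became 2. Another split of the C57BL/6J mice on these 2 diets also gave 37. Feature 40638 had the largest fall. In C57BL/6J mice on soy its mean was -3.12 ± 0.75, and in C57BL/6J mice on the other diets the means were between -0.22 and 0.66. Against the milk diets it fell by 3.56 on the log2 scale (SE 0.16, limma adjusted p = 5.14e-27). In knockout mice on soy its mean was 1.23 ± 0.21, against 1.37 ± 0.29 on AIN76A, and the difference in soy response between the strains was 2.76 (limma adjusted p = 4.84e-10). Feature 15364 fell by 3.36 on soy against milk in C57BL/6J and fell by 2.60 in the knockout (limma adjusted p = 1.55e-05 and 0.000551). Feature 43 rose by 2.21 on soy against milk in C57BL/6J, and feature 14940 by 1.55. Feature 14940 also rose in the knockout, by 1.28 (limma adjusted p = 0.000227). The soy against milk effects of the strains had a correlation of -0.08 across all features.

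**Figure D3:**
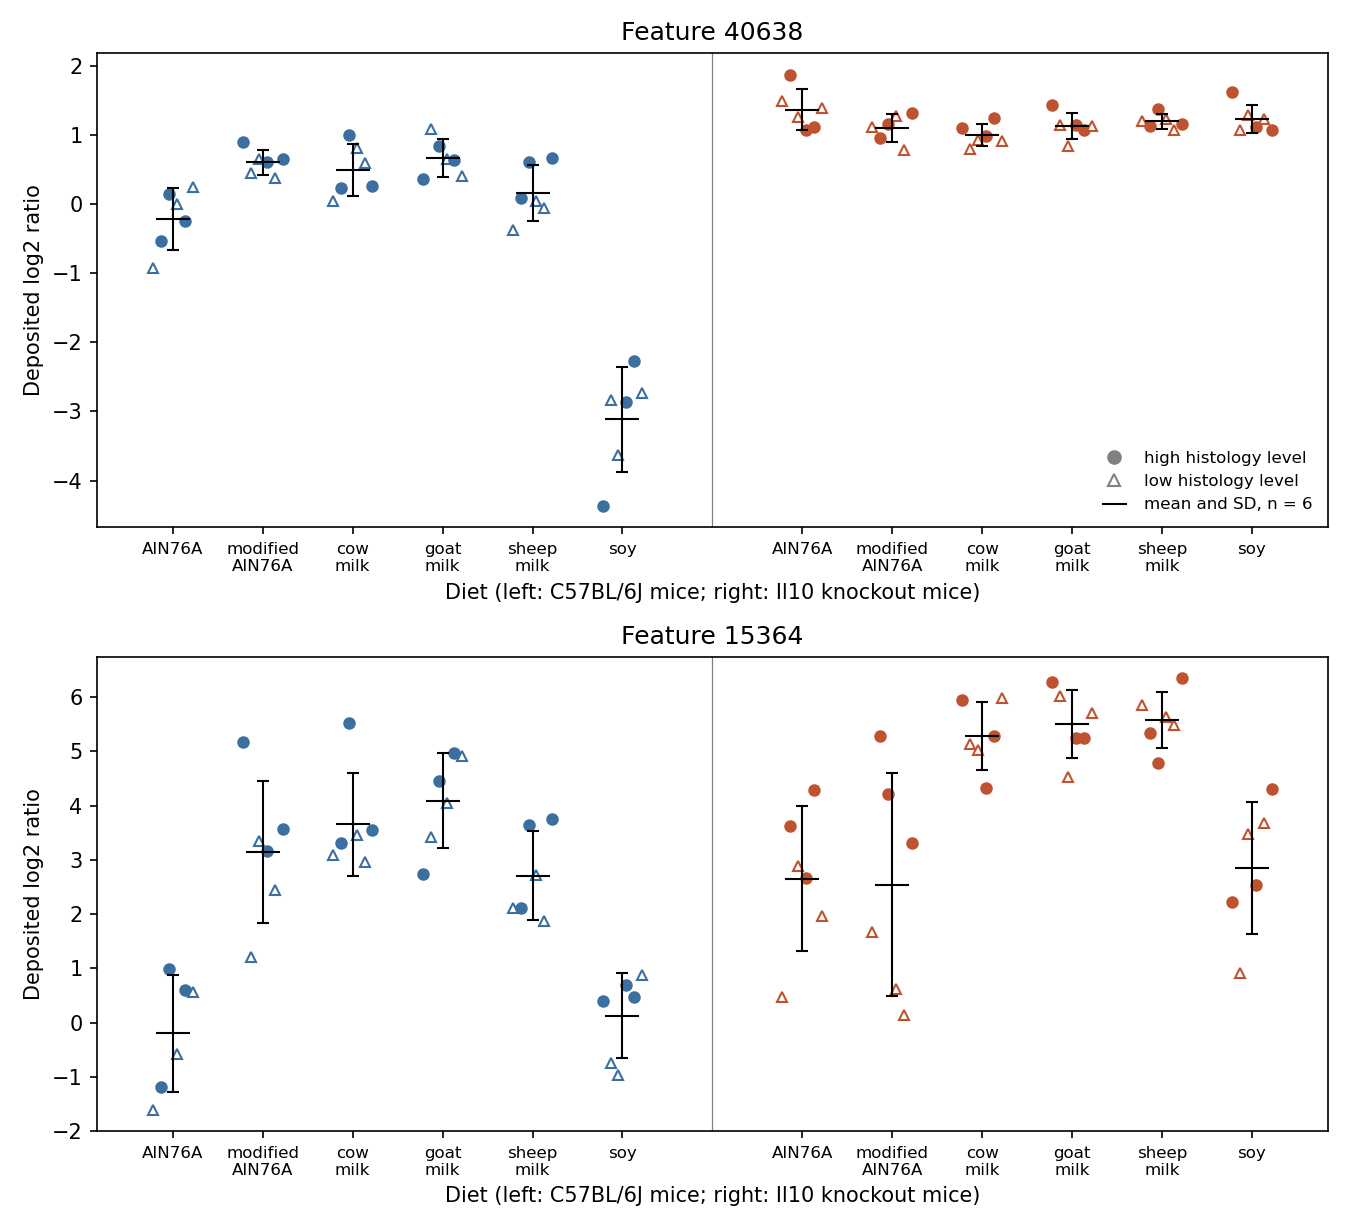
Deposited log2 ratios of features 40638 and 15364 in each mouse, by diet, with C57BL/6J mice on the left and Il10 knockout mice on the right. Filled circles are mice of a high and open triangles mice of a low histology level, and bars show the mean and SD of 6 mice. Feature 40638 had a mean of -3.12 in C57BL/6J mice on soy, and feature 15364 had means of 5.28, 5.51 and 5.58 in knockout mice on cow, goat and sheep milk.

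The modified AIN76A diet was compared with AIN76A. C57BL/6J mice had 652 changed features, 390 higher and 262 lower, and 632 of them moved in the direction of the knockout values. Of all features, called or not, 35.9% moved in the direction of C57BL/6J and the rest in that of the knockout. In the knockout 1 feature changed, where 3331 had an unadjusted p under 0.05 in limma, more than the chance share. The knockout count was 37 without the 8 arrays of large residual spread and 6 with array weights. It was 0 with slide as a fixed block or with the fit restricted to the arrays compared. The C57BL/6J count fell to 164 (76 higher, 88 lower) with slide as a fixed block. It fell to 86 (40 higher, 46 lower) when the fit was restricted to the arrays compared. A minimum change of 1.5-fold left 223 (73 higher, 150 lower). Leaving out slide 3 gave 130 (63 higher, 67 lower) and slide 11 gave 155 (73 higher, 82 lower). Leaving out slides 2, 6 and 14 gave 192, 310 and 317, and slide 9 gave 1175. The count rose to 1042 with quantile normalization and to 1417 without the 8 arrays of large residual spread. Feature 15364 had the largest rise, from -0.20 ± 1.07 on AIN76A to 3.15 ± 1.31 on modified AIN76A in C57BL/6J (SD, n = 6 each). Feature 23598 rose by 1.77, and features 11405 and 23736, which were lower in the knockout, changed by -3.09 and -2.75. On the strain axis, C57BL/6J mice on modified AIN76A lay at 0.20 ± 0.17 and those on AIN76A at -0.14 ± 0.12 (difference 0.34, exact permutation p = 0.00649, adjusted p = 0.0289). The same difference in the knockout was -0.14 (exact permutation p = 0.221, adjusted p = 0.34). With slide effects removed the differences were 0.28 in C57BL/6J and -0.07 in the knockout.

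The last comparison set mice of a high histology level against mice of a low level within the same diet groups, with 18 mice of each level per strain. In the knockout 37 features differed, 2 higher and 35 lower in high-level mice, and each of the 37 also differed between the strains, in the same direction. Of all features, 46.4% differed between the strains. Over all features the difference between levels had a correlation of 0.72 with the strain difference, so the shared direction is not particular to the 37. The largest rises were in features 7306 and 1734, by 0.90 (SE 0.20) and 0.84 (SE 0.19), and the largest falls were in features 17740 and 8719, by 0.92 (SE 0.20) and 0.80 (SE 0.15). The 37 features became 0 when the fit was restricted to the arrays compared and 2 without 8 arrays of large residual spread. They became 0 without slide 3, 4 or 9 and 123 without slide 7, and another split of the same mice gave 955. No feature differed in C57BL/6J mice in limma, where 3888 had an unadjusted p under 0.05, more than the chance share. The interaction of histology level with strain gave no feature, with 1653 at an unadjusted p under 0.05, fewer than the chance share. On the strain axis, high-level knockout mice lay at 1.07 ± 0.25 and low-level ones at 0.89 ± 0.21 (SD, n = 18 each, difference 0.18, permutation p = 0.00102 within diet groups, adjusted p = 0.0204). The high-level mean was above the low-level mean in 5 of the 6 knockout groups. In C57BL/6J mice the difference was 0.10, which did not pass the adjustment (permutation p = 0.0316, adjusted p = 0.079), and the high-level mean was above the low-level mean in 5 of the 6 groups.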

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

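The tests of slide effects, of arrays of large residual spread, of the ratio's direction and of other splits of the mice were chosen or given their criteria only after the related results had been seen. The tests of wrong strain labels and of array scaling were written down before their results were seen. The scaling test used the strain axis, which was itself chosen after the data were examined.

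Several strain differences depended on diet. The interaction of strain and diet was past the threshold for 2840 features, and the single interactions with AIN76A as baseline gave 1964 features for cow milk, 1650 for goat milk, 429 for modified AIN76A and 3 for soy. One mouse stood apart from its group on the strain axis. A C57BL/6J mouse on cow milk lay at 0.49 while the group's mean was 0.07, and its gap to the nearest mouse was 0.65 of the group's range. Chance gives such a gap in about 1 of 20 groups, and 12 groups were looked at. That mouse was of the high histology level and its array was among the 8 of large residual spread. Residuals are distances from the group mean, so a mouse far from its group tends to a large residual spread. The spread is therefore not independent evidence of a poor array.

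Knockout mice on cow and goat milk lay nearer to C57BL/6J mice on the strain axis than knockout mice on AIN76A. C57BL/6J mice on goat milk in turn lay nearer to the knockout than those on AIN76A (difference 0.2533, exact permutation adjusted p = 0.0289). The C57BL/6J cow milk difference, 0.1981, had the same direction but did not pass the adjustment (exact permutation adjusted p = 0.0866). For goat milk the shift was therefore not confined to the knockout. Slide effects as the whole cause are opposed by the cow milk difference, which was -0.3256 with slide effects removed (exact permutation p = 0.00216, which leaves out the error of the slide estimates). The counts of features did not hold in the same way, and fell with slide as a fixed block from 1964 to 198 in the cow milk interaction and from 1650 to 45 in the goat milk interaction, while the median sizes over those features went from 0.77 to 0.66 and from 0.75 to 0.62 and the standard errors rose from 0.13 to 0.15. Wrong strain labels are opposed by the 50 best strain features chosen without each mouse, since each of the 12 cow and goat milk arrays lay on the knockout side for at least 40 of them. Arrays of smaller range are opposed by scaling, since the difference was -0.3567 with every array scaled to the same SD. A diet effect on the colon may therefore underlie the pattern, as a hypothesis from the same data, and whether it reflects less inflammation, other cells in the sample or the choice of mice was not tested.

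Modified AIN76A changed 652 features in C57BL/6J and 1 in the knockout, and the difference between the strains was past the threshold for 429 features, a count that became 0 without slide 3 or slide 11 and 1104 without slide 10. With slide as a fixed block no interaction feature was left in limma, while the median ratio of the effects with the block to those without was 0.8612 over the 429 features. Their median size fell from 0.69 to 0.59 and the standard error rose from 0.13 to 0.14. Without the 8 arrays of large residual spread 31 interaction features were left, and the median ratio of effects was 0.8939. Modified AIN76A then changed 1417 features in C57BL/6J and 37 in the knockout. On the strain axis the C57BL/6J difference was 0.3412, or 0.3309 without those arrays and 0.2804 with slide effects removed. The knockout difference was -0.1419, or -0.1195 and -0.0743. None of those 8 arrays was of C57BL/6J mice on AIN76A or modified AIN76A, or of knockout mice on modified AIN76A. Some were of knockout mice on AIN76A. Those arrays could therefore account for part of the difference between the strains, but not for the change in C57BL/6J. Slide effects could account for part of the pattern and cannot be told apart from a diet effect here. Wrong strain labels are opposed by the 12 C57BL/6J arrays on both diets, each of which lay on the C57BL/6J side for at least 44 of 50 features.

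More features lay far above 0 than far below it. A mean over 3 was found in 745 features and a mean under -3 in 14. Transcripts of liver, kidney and fetus are missing from colon while intestine is part of the reference, so this asymmetry is consistent with a deposited ratio of reference over mouse, in which a higher ratio would be less RNA in the mouse. The opposite direction would put the excess below 0 only if the intestine in the reference held the colon's transcripts at a similar level. That was not tested, and neither was a feature's dye bias, so the direction is not settled. No biological explanation was tested for this pattern.

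Other splits of the same arrays were counted for each result, with 100 splits that include the real one. For the strain effect over all diets 1 split, the real one, gave as many features (20897, highest other 0). The strain effect on AIN76A likewise had 1 split (14656, highest other 9029). That is the smallest share that 100 splits can give, and it was not adjusted over the results tested. It argues against chance but does not exclude it. The same holds for the interaction with 1 split (2840, highest other 1), for diet in the knockout with 1 split (3990, highest other 578) and in C57BL/6J with 1 split (450, highest other 89), and for the milk diets among each other in the knockout with 1 split (1308, highest other 861). In C57BL/6J it holds for milk against AIN76A with 1 split (46, highest other 14), for soy against milk with 1 split (157, highest other 21) and for modified AIN76A with 1 split (652, highest other 51). The splits were counted for the main fit alone. The 46 features were 12 with slide as a fixed block, 11 with merged spots, 3 without slide 6 and 1 without slide 11. For 4 more results the share of such splits was also under 0.05, the criterion used here, but at least 1 other split reached the real count. Chance is therefore not excluded for these 4 results either. These were soy against AIN76A in C57BL/6J with 3 splits (37, highest other 37) and, in the knockout, milk against AIN76A with 2 splits (2209, highest other 2390), soy against milk with 2 splits (2084, highest other 2166) and histology with 4 splits (37, highest other 955). The 955 features of that other split are several times the real count, so a structure of the mice beyond histology level could be present, which was not tested. Chance is also not excluded for modified AIN76A in the knockout, where 32 splits gave as many (1, highest other 440). For soy against AIN76A in the knockout, histology in C57BL/6J and the histology interaction the real count was 0, all 100 splits gave as many, and the highest others were 364, 1 and 718.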

How the results depend on the processing

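Merging near-identical spots, leaving out arrays of large residual spread and all alternatives for positions were chosen after the data were examined; the other alternatives were fixed before. The cause of the changes listed here was not tested, except that a fold minimum, a fit to the compared groups and leaving out arrays each use fewer features or arrays by construction. Of the 204 values of the main feature counts under these alternatives, 153 stayed within 1.5 times of the reported count, 33 fell below and 18 rose above it. Of 306 further values with a slide left out, 257 stayed, 41 fell and 8 rose. The reported count was 0 for soy against AIN76A in the knockout, histology in C57BL/6J and the histology interaction. A count that stayed at 0 was taken as unchanged. For strain over all diets and the interaction, the fit to the compared groups gave the reported counts of 20897 and 2840, since it uses all arrays. No paired analysis was possible by label, because the labels give the mice no replicate numbers, and slides were used as blocks instead. Each slide held only some of the groups. Sets of consecutive slides that together held a mouse of every group were present, and they were not tested as blocks. The counts with slide as a block therefore do not show what such complete blocks would give. Gene list shifts, list levels per mouse, the marker check of the ratio's direction and the averaging of probes by gene were not run, since the features have no names. Signal over background is unknown, so the effect of dim features was not tested.

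With slide as a fixed block the counts were 412 for milk against AIN76A, 837 for soy against milk, 0 for modified AIN76A and 65 for histology in the knockout. In C57BL/6J they were 12 for milk, 19 for soy and 164 for modified AIN76A against AIN76A and 254 for diet, and the interaction had 1761. With slide as a random block histology in the knockout gave 67. Quantile normalization gave 57 for soy and 1042 for modified AIN76A against AIN76A and 758 for diet in C57BL/6J, and 12 for histology in the knockout. Fitting the compared groups alone gave 1335 for milk and 0 for modified AIN76A against AIN76A, 551 for the milk diets among each other and 0 for histology in the knockout. In C57BL/6J it gave 15 for milk, 2 for soy and 86 for modified AIN76A against AIN76A and 101 for soy against milk. Array weights gave 3352 for milk, 6 for soy and 6 for modified AIN76A against AIN76A, 4204 for soy against milk and 11 for histology in the knockout. In C57BL/6J they gave 22 for milk against AIN76A, 239 for soy against milk and 1201 for diet. The histology level as a term gave 56 for histology in the knockout. Keeping features with an SD above the median gave 1004 for modified AIN76A in C57BL/6J.

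A minimum change of 1.5-fold left 3261 features for strain over all diets and 5477 for strain on AIN76A. In the knockout it left 521 for milk against AIN76A, 568 for soy against milk, 1883 for diet, 762 for the milk diets among each other and 5 for histology. In C57BL/6J it left 20 for milk against AIN76A, 60 for soy against milk, 223 for modified AIN76A and 239 for diet. Merging near-identical spots gave 11 for milk against AIN76A in C57BL/6J and 17 for histology in the knockout. Without the 8 arrays of large residual spread the counts were 6 for soy and 37 for modified AIN76A against AIN76A and 2 for histology in the knockout, and 107 for milk, 1417 for modified AIN76A and 695 for diet in C57BL/6J.

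Leaving out each of the 18 slides in turn gave ranges that moved some counts by over 1.5 times. In the knockout these were 1183 (slide 4) to 2814 for milk against AIN76A, 919 (slide 16) to 2729 for soy against milk, with 1101 without slide 8, 645 (slide 5) to 1580 for the milk diets among each other, with 734 and 826 without slides 9 and 17, 0 to 3 for modified AIN76A, and 0 (slides 3, 4 and 9) to 123 (slide 7) for histology. In C57BL/6J they were 1 (slide 11) to 59 for milk and 23 (slides 10, 11 and 16) to 47 for soy against AIN76A, 93 (slide 8) to 179 for soy against milk, with 102 without slide 10, 130 (slide 3) to 1175 (slide 9) for modified AIN76A, 208 (slide 14) to 572 for diet, and 0 to 2 for histology.

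Of the 140 values of position differences under the alternatives, 132 kept their side of an unadjusted p of 0.05. Of the rest, goat against sheep milk in the knockout was -0.2574 with merged spots and -0.2241 with features scaled to equal SD. In C57BL/6J cow milk against AIN76A was 0.1458 with slide effects removed and 0.1096 without the arrays of large residual spread, and goat against sheep milk was 0.1857 with quantile normalization and 0.1573 without those arrays, each now missing the threshold. With slide effects removed cow against sheep milk and soy against milk in C57BL/6J came to 0.1791 and -0.1352 and passed it.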

Other observations

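Feature 15364 differed between soy and the milk diets in both strains. In the knockout its means were 5.28 ± 0.62 on cow milk, 5.51 ± 0.63 on goat milk and 5.58 ± 0.52 on sheep milk, against 2.65 ± 1.34 on AIN76A and 2.85 ± 1.22 on soy (SD, n = 6 each). In C57BL/6J its means on cow, goat and sheep milk were 3.65 ± 0.94, 4.09 ± 0.88 and 2.70 ± 0.82, against -0.20 ± 1.07 on AIN76A and 0.12 ± 0.78 on soy. On modified AIN76A its mean was 3.15 ± 1.31 in C57BL/6J and 2.54 ± 2.05 in the knockout. The sheep milk difference from AIN76A did not pass the threshold in either strain (limma adjusted p = 0.277 in the knockout and 0.297 in C57BL/6J). Its size in the knockout was 2.93. The cow and goat milk differences there were 2.63 and 2.86 and passed (limma adjusted p = 0.00256 and 0.00187). In C57BL/6J the sheep milk difference was 2.90, against 3.85 and 4.29 for cow and goat milk. The p-values were adjusted within each comparison, so the missed threshold does not show that sheep milk lacked the effect.

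On soy 26 features of C57BL/6J mice differed from AIN76A, from the milk diets and from modified AIN76A in the same direction, 4 higher and 22 lower on soy. In the knockout 3 of the 26 were past the threshold in that direction for soy against milk, and 22 had the same sign for soy against AIN76A.

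The cow and goat milk effects in the knockout were compared without shared mice. The effect of cow milk against modified AIN76A and that of goat milk against AIN76A had a correlation of 0.74 across features, and the exchanged pair had 0.71. For sheep milk against modified AIN76A and cow milk against AIN76A the correlation was 0.25. The difference between high and low histology levels had a correlation with the strain difference of 0.72 in the knockout and 0.43 in C57BL/6J, across features, which are not independent replicates. In the knockout the 3 high-level mice lay above the 3 low-level mice on the strain axis in 2 of the 6 diet groups, where chance gives this order in 5% of groups. In C57BL/6J this held in 1 of the 6 groups, and on soy the 3 high-level mice lay below the 3 low-level mice.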
